A study of Danio rerio with 24 samples.

How the data were processed

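Both RNA and DNA were measured. RNA was profiled in 20 libraries of fluorescence-sorted PGCs, prepared with a full-length mRNA amplification kit for single cells and a transposase library kit, at 75% epiboly and at 1 dpf. DNA from about 300 PGCs or somatic cells per group at the 15-somite stage was whole-genome amplified, and 3 target regions of the smad1 guide RNAs were amplified and pooled, giving 4 libraries. Groups, stages and replicate numbers were taken from the labels before the data were examined.

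The expression tables deposited by the authors hold TPM, with 1 column per library and 32520 genes in each of 4 tables. The submitters' processing notes name STAR 2.7.10b, StringTie 2.2.1 and the zebrafish build GRCz11 (danRer11) without stating what each was used for. The amplicon tables deposited by the authors hold read counts per amplicon. The same deposited tables also give percent modified, which was recomputed from the counts. The aligner and caller of the amplicons are not given in the sources used here, and substitutions were not counted as modifications. TPM keep no read depth, so the precision of each library is unknown. Of the features, 896 had no name, 533 names were used by more than 1 gene ID, and 44 were abundant ribosomal or mitochondrial features. All per-sample columns were used.

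TPM were transformed as log2(TPM + 1), and genes with a mean TPM of at least 1 over the libraries of a fit were kept. Each table was processed separately. Groups were compared with moderated t-tests in limma 3.58.1 with an intensity trend, under R 4.3.3, and p was adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The 4 comparisons were cKO against control and KD against control morpholino at each stage. The differences between stages within each experiment and the differences between the cKO and the KD at each stage were tested as contrasts. The average at each stage was fitted as 1 common effect with a term for the experiment. It thus weighs the cKO, which has more libraries, more than the KD. The gene lists, 32 in number and with at least 5 members tested, were fixed before the data were examined; the interferon and endothelium lists reached that size at 1 dpf only. Each list was tested with camera at a preset correlation of 0.01, and beside it with a correlation estimated from the data. A further list test, fry, was also run, and its results are not given here. Members were also adjusted over the list alone. Values relative to all genes are list medians minus the median of all genes tested. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

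The genes named were chosen by a rule written before the data were examined. It takes smad1, smad5 and smad9 in every library. It takes 12 genes per direction among called genes whose groups do not overlap, with an assigned symbol and a mean TPM of at least 5. Where fewer than 10 genes were called, it takes the 10 higher and the 10 lower genes with the smallest unadjusted p, named as not called. It takes up to 4 members of each list by p and up to 3 by level, and up to 6 genes by p for each difference. Genes outside the rule are marked as chosen after their values were seen.

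Editing was computed as modified over aligned reads, with 95% Clopper-Pearson intervals and two-sided Fisher's exact tests (scipy 1.17.1, numpy 2.4.6), adjusted over 12 tests. Correlations between log2 differences used genes tested in both comparisons, with exact permutation of the libraries within tables. Same-numbered libraries were taken as paired where there were at least 3 pairs and in each the deviations from the group means correlated above 0.1. In the cKO experiment all same-numbered pairs did so (0.176, 0.196 and 0.417 at 75% epiboly, 0.265, 0.105 and 0.272 at 1 dpf). The KD experiment has 2 same-numbered pairs per stage, too few for this rule, and its libraries are treated as sharing only a number. The main fits did not use the pairing, and the fit blocked on replicate number is given as an alternative. For the cKO at 1 dpf the blocked fit called 14 genes against 1 in the main fit. Averages and differences were not fitted with a block.

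The fits were tested on simulated data, in which 200 genes were changed by a log2 difference of 1, 2 or 3. A change of 1 was recovered for 0% of genes in the cKO at 75% epiboly and 20.9% at 1 dpf, a change of 2 for 11.9% and 76.1%, and a change of 3 for 31.8% and 89.4%. In the KD comparisons 0% was recovered at each size and stage. For the average at 1 dpf 37.3%, 85.1% and 92.4% were recovered, and at 75% epiboly 10.4%, 56.7% and 84.8%. For the difference between the cKO and the KD at 1 dpf the values were 1.49%, 23.9% and 56.1%, and at 75% epiboly 0%, 0% and 1.52%. For the stage difference they were 0%, 8.96% and 28.8% in the cKO and 0% throughout in the KD.

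The alternatives were a pseudocount of 0.1, no filter, a minimum mean of 5 TPM, quantile normalization, TMM-style scaling, no intensity trend, the replicate number as a block, each library left out in turn, and for editing the amplicons summed or the control subtracted. Added after the data were seen were leaving out the abundant features, leaving out both libraries numbered 3, the counts adjusted over a list alone under each alternative, and the list tests of averages and differences. Gene coordinates were not used. Some genes, and a gene list that rests on them, are not reported here.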

Results

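Primordial germ cells (PGCs), the embryonic founders of eggs and sperm, were sorted by their fluorescent label from zebrafish embryos in which smad1 had been lost in either of 2 ways. In the conditional knockout (cKO), guide RNAs against smad1 were used with a knockout restricted to the germline. In the knockdown (KD), embryos received a smad1 morpholino, an antisense oligomer that blocks the use of its target transcript throughout the embryo. RNA was profiled at 75% epiboly, during gastrulation, and at 1 day post-fertilization (1 dpf), in 3 control and 3 cKO libraries and in 2 control-morpholino and 2 KD libraries per stage, which gave 20 libraries. The comparisons address how BMP signalling, which acts through the transcription factors Smad1, Smad5 and Smad9, bears on PGC proliferation. The values were TPM, the length-scaled share of each transcript in its library, which keep no read depth, so the depth is unknown; between 13371 and 24547 genes per library had a TPM above 0. The labels name no separate clutches, so the limma p-values measure the spread between these libraries, which may be technical. The camera p-values at the preset correlation treat genes as nearly independent, so they do not measure that spread. By exact permutation of the libraries, the smallest possible p for a list mean was 0.1 in a cKO comparison and 0.333 in a KD comparison. The exact permutations took the libraries as unpaired and did not use the pairing of the cKO libraries.

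Editing of smad1 was read in DNA from about 300 sorted cells per group at the 15-somite stage, in 1 library per group without replicates. In cKO PGCs, 81.1% of aligned reads carried an insertion or deletion at the first target region (95% Clopper-Pearson interval 80.9 to 81.3%), 62.6% at the second (62.5 to 62.8%) and 37.2% at the third (36.9 to 37.5%). Control PGCs gave 0.306%, 0.156% and 1.28% at the same regions, and the intervals of the groups did not overlap. Somatic cells of the cKO embryos gave 0.476%, 0.156% and 1.38%, against 0.260%, 0.140% and 1.39% in control somatic cells. Among somatic cells only the first region differed between the 2 libraries (Fisher's exact test, two-sided, adjusted over 12 tests, p = 1.04e-19; p = 0.104 and p = 0.953 at the other regions), and that difference was 0.216 percentage points. Control PGCs and control somatic cells also differed at the first region (adjusted p = 0.0298, Fisher's exact test). The libraries held 405768 to 601814 aligned reads, but reads amplified from few genomes are not independent molecules, so the intervals cover counting error only and the tests compare libraries, not conditions.

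**Figure D1:**
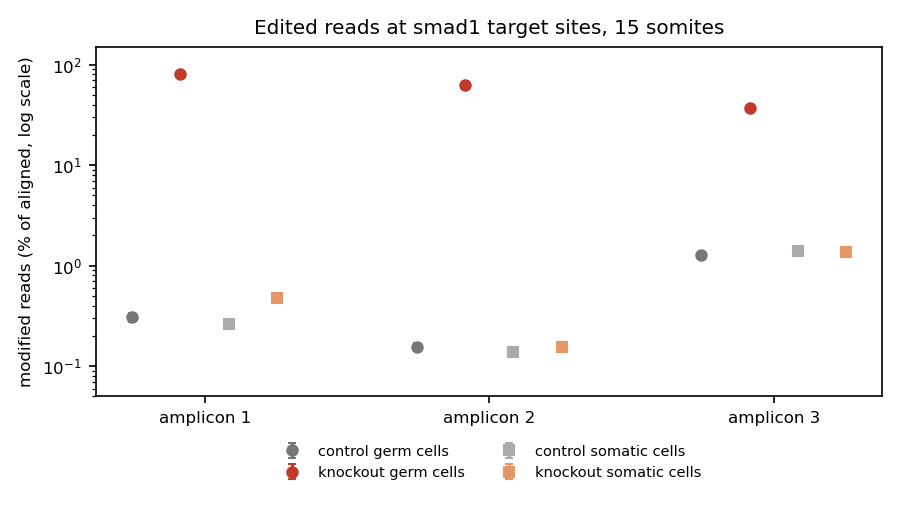
Percent of aligned reads with an insertion or deletion (log axis) at the 3 smad1 target regions in the 4 amplicon libraries; points are libraries and bars are 95% Clopper-Pearson intervals. The cKO PGC library lies at 37.2% to 81.1%, and the other libraries lie between 0.140% and 1.39%.

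The smad1 transcript itself was lower in every cKO library than in any control library at both stages. At 1 dpf the controls stood at 140.0, 140.0 and 134 TPM and the cKO libraries at 16.4, 12.5 and 11.7 TPM (138 ± 3.30 against 13.5 ± 2.52, mean ± SD, n = 3 each), and smad1 fell by 3.28 on the log2(TPM + 1) scale (SE 0.19, limma adjusted p = 5.27e-04). At 75% epiboly the control values were 9.68, 13.5 and 17.9 TPM and the cKO values 2.68, 1.11 and 5.09 TPM (13.7 ± 4.13 against 2.96 ± 2.01, n = 3 each), a log2 difference of -1.99 (SE 0.64) that did not pass the test (limma adjusted p = 1.00). In the KD experiment smad1 stood at 9.96 and 9.80 TPM in control-morpholino and at 2.60 and 4.23 TPM in KD libraries at 75% epiboly. At 1 dpf the corresponding values were 201 and 193 TPM against 170.3 and 70.28 TPM (log2 difference -0.84, SE 0.53, limma adjusted p = 0.673). A morpholino can act on translation alone, so the transcript level need not report its effect. Among the paralogs, smad9 averaged 34.8 TPM in control and 40.6 in cKO PGCs at 75% epiboly and 134 against 123 at 1 dpf, while smad5 averaged 95.1 against 82.7 and then 36.0 against 40.9. In the KD experiment smad9 stood at 58.2 and 45.8 TPM against 16.9 and 6.18 at 75% epiboly (log2 difference -2.21, SE 0.66, adjusted p = 1.00), and smad5 averaged 98.8 against 108. At 1 dpf the KD experiment had smad9 means of 54.3 and 33.9 TPM and smad5 means of 23.3 and 21.8 TPM, with no call by limma.

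**Figure D2:**
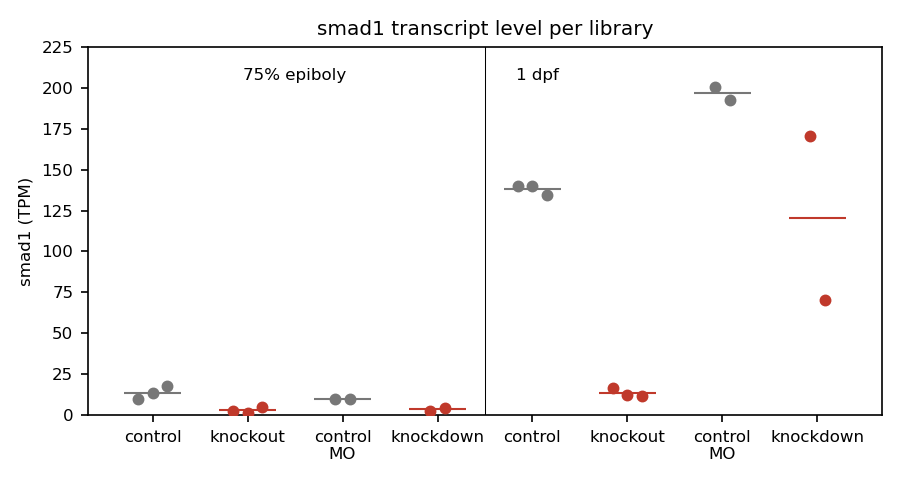
TPM of smad1 per library in the 4 comparisons; points are libraries and bars are group means. At 1 dpf the cKO libraries lie at 11.7 to 16.4 TPM against 134 to 140.0 TPM in controls, while the KD libraries lie at 70.28 and 170.3 TPM against 193 and 201 TPM.

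Germ cell transcripts were present in all 20 libraries, at very different levels. In the cKO experiment at 1 dpf, nanos3, which protects germ cell fate, averaged 12695 TPM in controls and 12486 in cKO PGCs, and ddx4, the germline helicase Vasa, averaged 529 and 528 TPM (n = 3 each). In the KD experiment at 1 dpf, nanos3 stood at 4165 and 1059.9 TPM in control-morpholino and at 3898 and 824 TPM in KD libraries. At 75% epiboly it ranged from 215 to 669.7 TPM in the KD experiment. In the cKO experiment at that stage nanos3 stood at 10621, 15551 and 2269.7 TPM in controls and 6856.5, 21249 and 2414.1 TPM in cKO libraries. There ddx4 ranged from 393.08 to 2544.6 TPM, against 105.85 to 225.28 TPM in the KD experiment. Of 31 germ cell specification and germ plasm genes, 19 were lower and 12 higher in control-morpholino than in control libraries at 75% epiboly. No member of the list of germ cell specification and germ plasm genes passed the test in any comparison, alone or over all genes, and the list was not called (median log2 difference 0.08 and 0.15 for the cKO at 75% epiboly and 1 dpf, -0.01 and -0.43 for the KD; camera adjusted p = 0.594, 0.377, 0.196 and 0.779). For the KD at 75% epiboly the median was negative and the camera direction positive, and the median was 0.26 after quantile normalization. For the KD at 1 dpf the median was 0.02 with TMM-style scaling. Transcripts of other cell types varied within groups. The keratin krt4, made by the skin, stood at 1243, 47.1 and 1.01 TPM in the controls and at 1568, 1894 and 0.755 TPM in the cKO libraries at 1 dpf. Globins made up 3.91% and 1.00% of all TPM in control-morpholino libraries and 5.82% and 13.1% in KD libraries at 1 dpf.

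At 75% epiboly few gene groups and no single gene passed a test in cKO PGCs. Among the genes with the smallest p, none of them called, the dorsal organizer gene admp, a BMP family ligand, stood at 10.9 ± 7.58 TPM in controls and 45.6 ± 27.2 in cKO PGCs, and the notochord regulator noto at 18.8 ± 9.30 and 67.1 ± 49.4 TPM (n = 3 each). Lower in the cKO were arpc4l (48.3 against 16.97 TPM), a subunit of the actin-nucleating Arp2/3 complex, drll.2 (28.0 against 7.12 TPM) and krt97 (13.8 against 2.95 TPM). The cytosolic ribosomal protein genes fell as a list by a median of 0.17 on the log2 scale, with 76 of 81 members below 0 and none passing alone (camera adjusted p = 0.0056; adjusted p = 0.971 with an estimated correlation). That call ended after quantile normalization (adjusted p = 0.391, median -0.04), without the abundant ribosomal and mitochondrial features (adjusted p = 0.192), without cKO replicate 2 (adjusted p = 0.260, direction higher) and without control replicate 3 (adjusted p = 0.838). BMP target genes had a median log2 difference of -0.08 with 12 of 27 above 0 (camera adjusted p = 0.830): the direct target id1 averaged 638 and 703 TPM, id3 90.2 and 45.3 TPM, and the ventral repressor ved 521 and 473 TPM. The G2/M and mitosis list had a median of -0.07 (adjusted p = 0.895). Nodal targets (median 0.14), neural genes (0.34) and lateral plate genes (-1.08) each reached a camera adjusted p of 0.0512 and were not called. limma called 0 of 13006 genes, with 236 genes at an unadjusted p under 0.05 against 650 expected by chance. Groups of 3 and 3 libraries separate by chance for 10% of genes, and 5.21% did so here. This chance value and the 650 genes take the libraries as unpaired.

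At 1 dpf the genes of mitosis were higher in cKO PGCs as a group. All 54 measured members of the G2/M and mitosis list had higher values in the cKO, with a median log2 difference of 1.11 (2.16-fold), and 47 rose with p adjusted over the list alone. The spindle protein nusap1 stood at 56.3 ± 10.2 TPM in controls and 224 ± 68.5 in cKO PGCs, the central spindle bundler prc1b at 12.6 and 70.6 TPM, the mitotic kinase aurka at 14.5 and 55.6 TPM, and the checkpoint protein mad2l1 at 213 and 676 TPM (n = 3 each). The abundant cell cycle kinase cdk1 rose from 439 to 865 TPM and cyclin ccnb3, chosen after its values were seen, from 54.2 to 137 TPM by the same adjustment. Over all genes tested none of the 54 was called (nusap1 log2 difference 1.94, SE 0.24, limma adjusted p = 0.0984), with 47 at an unadjusted p under 0.05, and with the replicate number as a block 1 was, prc1b (adjusted p = 0.0179). The list rose by camera (adjusted p = 2.5e-50), but not with an estimated correlation (adjusted p = 0.347). Exact permutation of the list's library means gave p = 0.1, the smallest possible for these libraries when taken as unpaired. Same-numbered control and cKO libraries differed by a median of 1.50, 1.24 and 0.51 in pairs 1, 2 and 3, where 52, 53 and 49 members were higher in the cKO. Somatic transcripts moved with the list in pairs 1 and 2, in which the endoderm, yolk and liver list differed by 1.87 and 1.44 and the skin list by 0.58 and 4.13, and not in pair 3 (-0.06 and 0). The number of members passing alone was 31 without cKO replicate 1, and likewise 31 without cKO replicate 2.

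**Figure D3:**
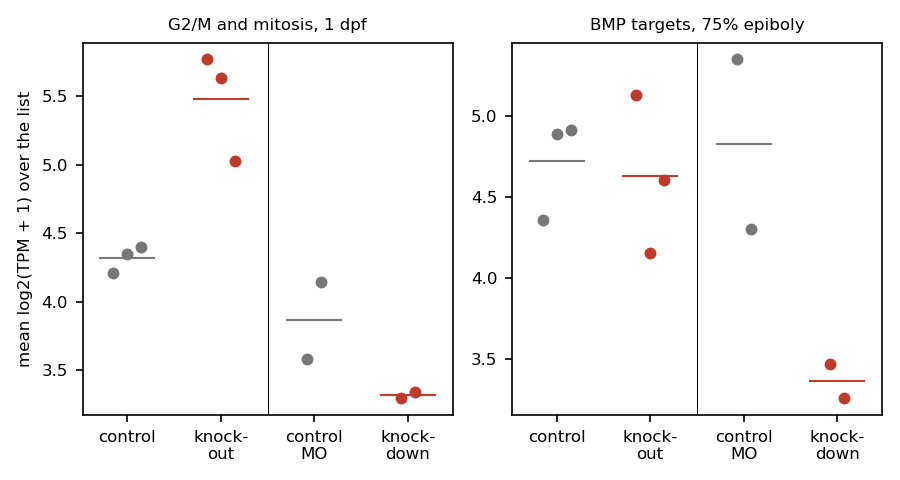
Mean log2(TPM + 1) over the members of 2 gene lists in each library, with points for libraries and bars for group means: the mitosis list at 1 dpf and BMP targets at 75% epiboly, for the cKO and KD experiments. The mitosis list averages 4.32 ± 0.10 in controls and 5.48 ± 0.39 in cKO PGCs (n = 3 each) and 3.86 ± 0.40 in control-morpholino and 3.32 ± 0.03 in KD PGCs (n = 2 each).

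Further lists rose by camera at 1 dpf in the cKO, in part with transcripts of other cell types. Of 25 skin genes, 24 were above 0 (median 1.50), of 19 endoderm, yolk and liver genes 17 (median 0.86), and of 17 blood genes 13 (median 0.80). The camera adjusted p were 5.4e-05, 4.5e-05 and 0.0034, against adjusted p = 0.635, adjusted p = 0.425 and adjusted p = 0.425 with an estimated correlation. The tight junction gene cldni (4.16 against 51.8 TPM) was the only skin gene to pass over the list alone, and no endoderm or blood gene did, though 9 endoderm genes did so in the fit blocked on replicate number. Both gene IDs named afp4, a liver secretory gene, were listed at 0 in all controls, and the more abundant stood at 35.4, 71.5 and 0 TPM in the cKO libraries. In pair 3 these lists differed by 0, -0.06 and 0. The skin call ended without cKO replicate 2 (adjusted p = 0.112) or control replicate 3 (adjusted p = 0.0658), and the blood call without control replicate 1 (adjusted p = 0.0655) or with a minimum mean of 5 TPM (adjusted p = 0.252). Genes of the first zygotic wave also rose (16 of 19 above 0, median 0.67, camera adjusted p = 1.1e-04; adjusted p = 0.347 with an estimated correlation), among them the ubiquitin-like isg15 at 439 and 1203 TPM and the ventral repressor vox at 1.03 and 10.1 TPM. No early zygotic gene passed over the list alone, and 6 did in the blocked fit. The list of G1/S and DNA replication genes rose slightly (41 of 52 above 0, median 0.18, camera adjusted p = 8.7e-04; adjusted p = 0.542 with an estimated correlation), with the sliding clamp pcna at 464 and 621 TPM and the histone chaperone chaf1a at 78.1 and 129 TPM. That call ended without control replicate 2 (adjusted p = 0.372). Genes of the cytoskeleton, adhesion and migration rose by a median of 0.23 (30 of 38 above 0, camera adjusted p = 0.0075, or adjusted p = 0.347 with an estimated correlation). The chemokine cxcl12b stood at 3.24 and 14.5 TPM, and the call ended without cKO replicate 1 (adjusted p = 0.0675). The library means of the early zygotic, G1/S and cytoskeleton lists overlapped between groups (exact permutation p = 0.3, 0.2 and 0.2).

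Respiratory chain genes were called slightly lower by camera in cKO PGCs at 1 dpf, but the library means of both lists overlapped between groups. Exact permutation of those means gave p = 0.2 for the nuclear and p = 0.6 for the mitochondrial list. The 95 nuclear genes of oxidative phosphorylation fell as a list by a median of 0.11 on the log2 scale, with 19 above 0 and none passing alone (camera adjusted p = 1.1e-04; adjusted p = 0.425 with an estimated correlation). The complex IV subunit gene cox6b1 stood at 271 and 165 TPM. The 36 features of the mitochondrial genome fell by a median of 0.17 (camera adjusted p = 0.0053; adjusted p = 0.425 with an estimated correlation), with the complex IV genes mt-co2 at 5593 and 4735 TPM and mt-co3 at 5318 and 4424 TPM. The mitochondrial call ended without cKO replicate 3 (adjusted p = 0.184) and without control replicate 2 (adjusted p = 0.106). BMP targets were not called in the cKO at 1 dpf: 14 of 29 were above 0, the median was -0.01, and camera gave a positive direction (adjusted p = 0.486). The ectodermal regulator foxi1 rose over the list alone (18.3 against 79.8 TPM), 3 BMP targets did so in the blocked fit, and id1 averaged 698 and 639 TPM. Of the BMP ligands, receptors and Smads only smad1 passed (21 measured, camera adjusted p = 0.747). Wnt targets were not called (9 of 11 above 0, median 0.21, camera adjusted p = 0.0806), though the Wnt antagonist dkk1b rose over the list alone (0, 0.258 and 1.38 against 12.2, 69.5 and 3.79 TPM, log2 difference 3.52, or 2.47 without cKO replicate 2). The piRNA pathway list, the germline defence against transposons, had a median of -0.23 (adjusted p = 0.147). The apoptosis list was not called (12 of 25 above 0, median -0.04, camera direction positive, adjusted p = 0.870), though 1 member passed over the list alone. Lists without a call included neural genes (median -0.20, adjusted p = 0.685), endothelium (-0.67, 0.191) and lateral plate (0.34, 0.546).

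Over all 17573 genes tested at 1 dpf, limma called 1 gene lower in the cKO, smad1, and 0 higher, with 1122 genes at an unadjusted p under 0.05 against 879 expected by chance. Next to it, with limma adjusted p = 0.0984 each, were nusap1, the CDK-binding protein cks2 (29.4 against 173 TPM), the RNA-processing gene lsm6 (333 against 149.95 TPM) and mmaa (46.8 against 14.7 TPM), a gene of vitamin B12 metabolism. With the replicate number as a block, 12 genes were higher and 2 lower, among them cks2, prc1b and the stress sensor sesn3 (11.7 against 44.3 TPM) as higher and smad1 and lsm6 as lower. Without cKO replicate 3, 45 genes were higher, and without control replicate 1, 2 genes were lower. The muscle light chain gene myl13 stood at 0.181 and 57.1 TPM (log2 difference 4.86, not called). Control and cKO libraries did not overlap for 11.4% of genes, against 10% by chance. This chance value and the 879 genes take the libraries as unpaired.

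In the KD at 75% epiboly, BMP target genes were lower as a group. Of 27 measured members only 2 were above 0, the median log2 difference was -1.42, and 6 fell with p adjusted over the list alone, while none was called over all genes. These were bambia, a BMP pseudoreceptor (164 against 26.6 TPM), the secreted ventral factor szl (39.2 against 0.857 TPM), ved (818 against 230.1 TPM), eve1 (165 against 40.8 TPM), the epidermal regulator tp63 (15.9 against 1.85 TPM) and msx1a (15.98 against 1.80 TPM, chosen after its values were seen), each n = 2. The direct target id1 averaged 1006 and 716 TPM. The list fell by camera (adjusted p = 7.6e-23, or adjusted p = 0.618 with an estimated correlation). Exact permutation of the list's library means gave p = 0.333, the smallest possible for these libraries. The count of 6 became 0 without control-morpholino replicate 1, without control-morpholino replicate 2, without KD replicate 2, with no filter and without the intensity trend.

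Endoderm and skin genes were lower in the same KD libraries. Of 22 endoderm, yolk and liver genes 4 were above 0 (median -1.53) and 6 fell over the list alone, among them the lipoprotein genes apoc1 (1508 against 282 TPM) and apoeb (1615 against 512 TPM) and the endoderm regulators sox32 (148 and 17.9 against 2.60 and 2.81 TPM, log2 difference -3.84, or -2.35 without control-morpholino replicate 1) and sox17 (28.7 and 5.76 against 0 and 0.902 TPM, chosen after its values were seen). The list fell by camera (adjusted p = 2.3e-11; adjusted p = 0.618 with an estimated correlation), a call that ended without KD replicate 1 (adjusted p = 0.172). Of 24 skin genes 2 were above 0 (median -1.38, camera adjusted p = 7.8e-09; adjusted p = 0.736 with an estimated correlation). The skin gene icn alone passed over the list (50.5 and 13.8 TPM in controls and listed at 0 in both KD libraries). The skin call ended without control-morpholino replicate 1 (adjusted p = 0.385, direction higher), in which krt18a.1 stood at 566 TPM against 30.7 TPM in the other control library. Early zygotic genes fell by a median of 0.71 with 4 of 28 passing alone, including the segmentation gene her7 (73.5 against 12.9 TPM), by camera with adjusted p = 6.8e-07 (adjusted p = 0.618 with an estimated correlation), but not without KD replicate 1 (adjusted p = 0.783, direction higher). Axial mesoderm genes were not called (9 of 12 above 0, median 0.58, adjusted p = 0.117), with the notochord regulator tbxta at 204 and 219.7 TPM, and neural genes had a median of -0.13 (adjusted p = 0.863).

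Growth-related and signalling lists were lower in the KD at 75% epiboly as well. Ribosomal protein genes fell by a median of 0.51 (79 of 81 below 0, none passing alone, camera adjusted p = 1.8e-24; adjusted p = 0.655 with an estimated correlation), with rps20 at 3518 and 2013 TPM. The proteasome list (median -0.33), ribosome biogenesis (-0.36) and oxidative phosphorylation (-0.25) fell with camera adjusted p of 1.5e-04, 7.4e-04 and 0.0010, against adjusted p = 0.618, adjusted p = 0.736 and adjusted p = 0.655 with an estimated correlation. Wnt targets (median -0.65) included the posterior gene cdx4 (323 against 136 TPM) and sp5l (179.9 against 93.2 TPM). The BMP ligand and receptor list (median -0.38) included bmp7a (25.3 against 3.498 TPM) and bmp2b (17.6 against 3.74 TPM). Both fell by camera, as did the cytoskeleton (-0.39) and muscle (-0.28) lists (adjusted p = 0.0035, 0.0088, 0.0051 and 0.0078), and none held with an estimated correlation (adjusted p = 0.618, adjusted p = 0.736, adjusted p = 0.866 and adjusted p = 0.618). Maternal transcripts rose by a median of 0.11 (26 of 41 above 0, camera adjusted p = 0.0040; adjusted p = 0.866 with an estimated correlation), with the maternal ligand gdf3 at 66.5 and 190.1 TPM.

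Most of these calls ended when 1 library was left out. That leaves a lone library in a group, so loss of power and dependence on that library cannot be told apart. Without KD replicate 1 only 4 lists were called lower, and the calls ended for the Wnt (adjusted p = 0.158), BMP ligand (0.161), ribosome biogenesis (0.0540), cytoskeleton (0.0589), muscle (0.484), oxidative phosphorylation (0.410), proteasome (0.0540) and maternal lists (0.508, direction lower). Without KD replicate 2 the BMP ligand (0.129), cytoskeleton (0.128) and muscle (0.0588) calls ended. Without control-morpholino replicate 1 the BMP ligand (0.240), Wnt (0.0570), cytoskeleton (0.333) and maternal (0.0765) calls ended, and without control-morpholino replicate 2 the ribosome biogenesis (0.0882), muscle (0.0882) and proteasome (0.185) calls. The muscle call also ended without the abundant features (adjusted p = 0.230). limma called 0 of 12968 genes, with 164 at an unadjusted p under 0.05 against 648 expected by chance. An alternative fit blocked on replicate number called 8 higher and 19 lower, but 2 same-numbered pairs cannot show whether the libraries were paired. Among the genes with the smallest p in the main fit, none called there, were the survivin gene birc5b (21.5 against 223 TPM) and the metallothionein mt2 (103 against 344 TPM). Others were the repressor her9 (5.95 against 29.2 TPM) and the ectodermal gene dlx3b (41.6 against 4.11 TPM).

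In the KD at 1 dpf the median log2 difference of all genes was -0.38, and it was 0.02 with TMM-style scaling and 0.01 after quantile normalization, so list medians are also given relative to all genes. Muscle genes were far lower: 25 of 26 were below 0, the median was -2.80 (-2.42 relative to all genes), and 18 fell with p adjusted over the list alone. They included troponin tnnt3b (42.3 against 0.713 TPM), tropomyosin tpma (33.5 against 1.93 TPM), parvalbumin pvalb1 (156 against 3.88 TPM) and the actin actc1b (372 against 38.9 TPM), each n = 2. The muscle list fell by camera (adjusted p = 4.0e-21; adjusted p = 0.658 with an estimated correlation). Blood genes were higher, with 25 of 30 above 0, a median of 0.99 (1.37 relative) and 12 members rising over the list alone, such as the embryonic globins hbae3 (1787 against 9085 TPM), hbbe3 (2922 against 8972 TPM) and hbbe1.1 (6303 against 25482 TPM). The blood list rose by camera (adjusted p = 2.4e-23; adjusted p = 0.658 with an estimated correlation). Its 12 members became 0 with TMM-style scaling, after quantile normalization, with no filter, without the intensity trend and without either KD library, 3 without control-morpholino replicate 2 and 5 without the abundant features. Muscle, blood and axial mesoderm are somatic cell types. Their genes were already higher in control-morpholino libraries than in controls of the cKO experiment (median log2 differences 2.29, 3.18 and 1.91). A different share of somatic cells in the KD libraries was not tested as a cause of these shifts. Axial mesoderm genes fell by a median of 0.99 (-0.62 relative), with 6 of 22 passing alone, such as tbxta (22.5 against 2.44 TPM) and the collagen col2a1a (19.4 against 2.40 TPM). That list fell by camera with adjusted p = 0.0323 (adjusted p = 0.669 with an estimated correlation), but not without control-morpholino replicate 1 (0.776), KD replicate 1 (0.666) or KD replicate 2 (0.335), or with a minimum mean of 5 TPM (0.288).

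Mitotic genes and BMP targets were not called in KD PGCs at 1 dpf. The mitosis list was not called (5 of 53 above 0, median -0.49, -0.11 relative, adjusted p = 0.203), with nusap1 at 53.8 and 20.5 TPM. BMP targets were not called either (7 of 29 above 0, median -0.52, -0.15 relative, adjusted p = 0.779), though ved (16.7 against 2.204 TPM) and msx2a (9.01 against 1.63 TPM) fell over the list alone.

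Several germline, housekeeping and signalling lists were also called in the KD at 1 dpf. All 17 piRNA pathway genes were below 0 (median -1.01, -0.64 relative), and 2 fell over the list alone, fkbp6 (14.1 against 1.83 TPM) and gpat2 (12.7 against 2.62 TPM). The list fell by camera (adjusted p = 0.0013; adjusted p = 0.869 with an estimated correlation), but not without KD replicate 2 (0.110) or control-morpholino replicate 1 (0.0900). KD replicate 2 also held the most globin transcripts and had ddx4 at 77.2 and dazl at 22.3 TPM, against 148 to 166 and 121 to 200 TPM in controls and 215 and 80.4 TPM in KD replicate 1. Compared with control-morpholino replicate 2, its dnd1 was also lower (31.3 against 82.9 TPM). Other germ cell genes set these 2 libraries less apart: nanos3 (824 against 1059.9 TPM), tdrd7a (28.2 against 31.8 TPM) and ca15b (38.4 against 18.9 TPM). Mitochondrial genome features rose (median 0.19, 0.57 relative, camera adjusted p = 8.6e-07; adjusted p = 0.658 with an estimated correlation), but not without KD replicate 2 (0.157). Wnt targets rose as a list (median 0.16, 0.53 relative, adjusted p = 0.0021; adjusted p = 0.658 with an estimated correlation), with the Wnt antagonist dkk1b at 2.01 and 0.669 TPM in control-morpholino and 6.57 and 45.6 TPM in KD libraries, but not without control-morpholino replicate 2 (0.0548). Heat shock genes (21 of 41 above 0, median 0.03, mean -0.01, 0.41 relative) and interferon and innate immune genes (9 of 18 above 0, median 0.13, 0.50 relative) were called higher (adjusted p = 0.0079 and 0.0187; adjusted p = 0.658 and adjusted p = 0.869 with an estimated correlation), while the chaperone hspa8 stood at 1289.7 and 587 TPM. Of the second list, the interferon regulator irf7, chosen after its values were seen, stood at 24.9 and 13.1 TPM. The chemokine cxcl18b stood at 10.7 and 29.5 TPM. Both calls ended after quantile normalization (0.0584 and 0.134), without KD replicate 2 (0.907 and 0.386) and without control-morpholino replicate 1 (0.0790 and 0.118), and the interferon call also without the abundant features (0.0604). Ribosomal proteins (median -0.45, -0.08 relative, but 0.02 with TMM-style scaling), G1/S genes (-0.62, -0.24 relative) and glycolysis (-0.67, -0.29 relative) fell by camera with adjusted p of 0.0040, 0.0212 and 0.0291, against adjusted p = 0.869, adjusted p = 0.869 and adjusted p = 0.669 with an estimated correlation. Without KD replicate 1 these calls ended (0.307, 0.573 and 0.592), as did the first and second without control-morpholino replicate 2 (0.256 and 0.552) and the third without control-morpholino replicate 1 (0.118) or the abundant features (0.0871).

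Single genes with large differences in the KD at 1 dpf did not pass the test. The melanin enzyme tyr stood at 3.42 and 82.1 TPM (log2 difference 4.18, limma adjusted p = 0.0505) and the melanosome gene pmela at 1.16 and 24.5 TPM (3.48, adjusted p = 0.0633). The neurexin nrxn3a stood at 32.0 and 0.769 TPM (-4.22, adjusted p = 0.0505) and the catenin ctnna2 at 57.2 and 2.697 TPM. Within the list of neural and neural crest genes, which was not called (15 of 36 above 0, median -0.52, camera direction positive, adjusted p = 0.381), tyr, pmela and hoxb1b (7.15 against 37.0 TPM) rose over the list alone, and fabp7a (331 against 90.3 TPM) and zic1 (14.0 against 2.13 TPM, chosen after its values were seen) fell. The retinoic acid enzyme cyp26a1 stood at 79.1 and 371 TPM. The posterior gene hoxb13a was listed at 0 in both KD libraries. limma called 0 of 17141 genes, with 1697 at an unadjusted p under 0.05 against 857 expected by chance. With a minimum mean of 5 TPM, 10 genes were higher and 33 lower, and without the intensity trend 1 and 9. In the fit blocked on replicate number they were 130 and 736, but 2 same-numbered pairs cannot show whether the libraries were paired. Without control-morpholino replicate 1 the counts were 8 and 33, and without control-morpholino replicate 2 they were 1 and 4. At 40.3% of genes the groups did not overlap, against 33.3% by chance for 2 and 2 libraries.

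Averaged over both ways of losing smad1, with more weight on the cKO and its larger number of libraries, the mitosis list was higher at 1 dpf. Of 54 members 50 were above 0, the median was 0.48 (0.64 relative to a median of -0.16 over all genes), and none passed over the list alone, while the median in the KD itself was -0.49. The list rose by camera (adjusted p = 4.2e-19; adjusted p = 0.528 with an estimated correlation). The gene sesn3 had an average log2 difference of 1.68 (SE 0.24, limma adjusted p = 0.0974). At 75% epiboly the average effect lowered BMP targets (25 of 27 below 0, median -0.71, camera adjusted p = 6.7e-09; adjusted p = 0.633 with an estimated correlation), with medians of -1.42 in the KD and -0.08 in the cKO, and smad1 itself had an average log2 difference of -1.72 (SE 0.45, not called). limma called 0 genes for the average at 75% epiboly and at 1 dpf, with 281 of 13236 and 1504 of 17965 genes at an unadjusted p under 0.05.

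The effect on mitotic genes differed between the cKO and the KD experiment by camera at the preset correlation. The 2 experiments also differ in their controls and in the germ cell and globin transcripts of their libraries. The differences below thus cannot be assigned to the way smad1 was lost. At 1 dpf all 54 members had a higher effect in the cKO than in the KD (median difference 1.59, 1.21 relative to all genes), and 40 passed over the list alone, 20 after quantile normalization, 4 with TMM-style scaling and 1 without control-morpholino replicate 2 (camera adjusted p = 4.2e-25; adjusted p = 0.265 with an estimated correlation). Muscle genes differed by a median of 2.89 (2.51 relative, adjusted p = 1.3e-12; adjusted p = 0.223 with an estimated correlation). At 75% epiboly BMP targets differed by a median of 1.65, with 22 of 27 less reduced in the cKO and 2 passing alone (adjusted p = 2.0e-14; adjusted p = 0.426 with an estimated correlation). For single genes at 1 dpf limma called 32 with a higher and 1 with a lower effect in the cKO, the latter pmela, named after its values were seen. The DNA repair gene palb2 (log2 difference 3.68, SE 0.40, adjusted p = 0.00992) and ndrg3b (3.31, adjusted p = 0.00992) led, followed by the small GTPase rhocb (2.74, adjusted p = 0.0217). Those counts were 0 and 0 without control-morpholino replicate 2, without cKO replicate 1 or 2, or without any 1 control library, 7 and 1 after quantile normalization and 5 and 1 with TMM-style scaling, by which the median over all genes went from 0.38 to -0.03 and 0.01. They were 2 and 0 without control-morpholino replicate 1, and 1356 and 55 without KD replicate 1. They were also 16 higher without cKO replicate 3 and 5 lower without KD replicate 2. At 75% epiboly 0 genes were called by limma, with 175 of 13236 at an unadjusted p under 0.05.

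**Figure D4:**
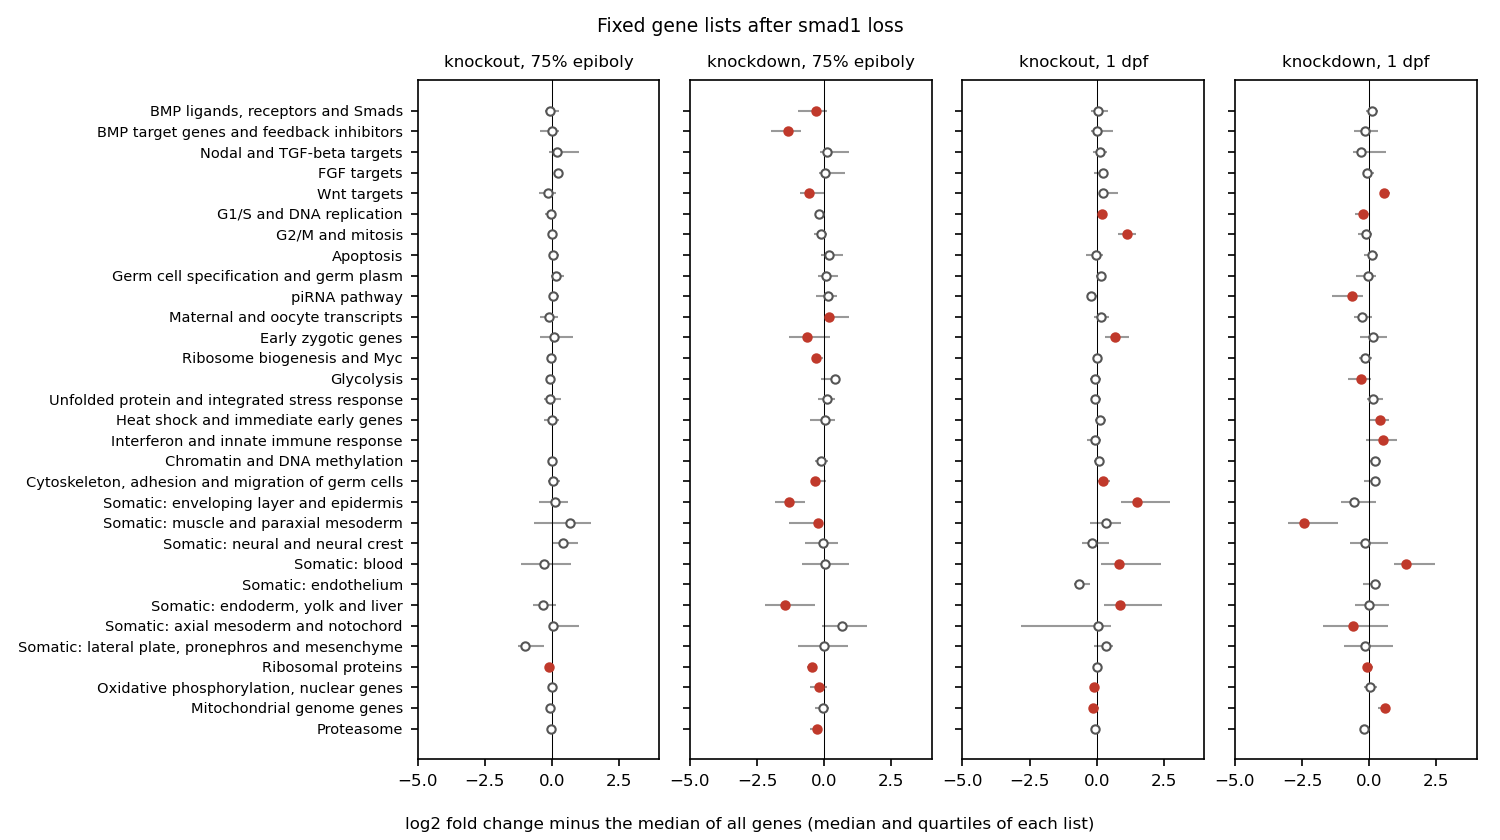
Median log2 difference of the gene lists minus the median of all genes, in the 4 comparisons; bars are quartiles over the list's genes, and filled red points have a camera adjusted p below 0.05 with the preset correlation of 0.01. The mitosis list stands at 1.13 in the cKO and at -0.11 in the KD at 1 dpf, and BMP targets stand at -0.01 in the cKO and -1.36 in the KD at 75% epiboly.

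The effects on some lists also differed between the stages by camera at the preset correlation, and none did with an estimated correlation. In the cKO the mitosis list had a higher effect at 1 dpf than at 75% epiboly for all 54 members (median 1.11, 7 passing alone, camera adjusted p = 9.3e-28; adjusted p = 0.311 with an estimated correlation). In the KD the BMP targets had a higher effect at 1 dpf, that is, were less reduced (23 of 32 members, median 0.68, or 1.02 with TMM-style scaling, adjusted p = 2.4e-09; adjusted p = 0.269 with an estimated correlation). Muscle genes in the KD had a lower effect at 1 dpf (median -2.46, camera adjusted p = 2.6e-11, or adjusted p = 0.269 with an estimated correlation). Of the 31 members in this contrast, only 9 passed the filter at 75% epiboly alone. Members near 0 TPM at 75% epiboly cannot fall there, so the contrast largely restates the effect at 1 dpf. No single gene was called by limma in either stage difference, with 628 of 16567 genes in the cKO and 695 of 16311 in the KD at an unadjusted p under 0.05. These fits left the pairing of the cKO libraries aside. The kinetochore gene nuf2 (2.37) and the muscle gene myl13 (4.86) were among those with the smallest p in the cKO, and the thyroid and kidney regulator pax8 (4.52) and tnnt3b (-4.49) in the KD.

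Across genes, the effects of the cKO and the KD showed little correlation. Pearson's r of the log2 differences was 0.00184 over 11707 genes at 75% epiboly (Spearman's rho 0.0240) and 0.0788 over 15532 genes at 1 dpf (rho 0.0866), with two-sided exact permutation p of 0.967 and 0.367 for r. Between stages r was 6.17e-04 in the cKO (rho -0.00359, exact permutation p = 0.97) and 0.00185 in the KD (rho 0.0250, exact permutation p = 1, where 0.111 is the smallest possible). Over these 4 relations the adjusted p was 1 for r and 0.88 for rho. Genes are not independent replicates, and the permutations exchanged libraries, not genes.

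Several lists had no call in any of the 4 comparisons of smad1 loss with its control. FGF targets had medians of 0.16 and 0.20 in the cKO and -0.05 and -0.44 in the KD (75% epiboly and 1 dpf in turn; the last was -0.10 with TMM-style scaling), with spread on both sides of 0. Genes of the unfolded protein and integrated stress response had medians of -0.13, -0.06, 0.05 and -0.24, and chromatin and DNA methylation genes -0.05, 0.09, -0.20 and -0.16, in the same order. For the KD at 1 dpf these were 0.16 and 0.26 with TMM-style scaling. Nodal targets (0.12 at 1 dpf in the cKO, 0.04 and -0.68 in the KD) and apoptosis genes (-0.03 at 75% epiboly in the cKO, 0.13 and -0.27 in the KD) likewise had no call. In the KD at 1 dpf the median of all genes was -0.38, so the apoptosis median lies above it and the Nodal median below. The smallest camera adjusted p among these 5 lists was 0.0512, for Nodal targets in the cKO at 75% epiboly.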

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

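Differences between stages or between the ways of losing smad1 were tested as contrasts; all tests of explanations in this part were chosen after the result was seen, except the counts of genes called in other splits of the libraries, which were planned. In the cKO 8 lists had a higher and 1 a lower effect at 1 dpf than at 75% epiboly, and in the KD 12 and 5. Between the cKO and the KD, 10 lists had a higher and 1 a lower effect in the cKO at 75% epiboly, and 6 and 2 at 1 dpf. For single genes at 1 dpf, 32 had a higher and 1 a lower effect in the cKO. None of these list differences was called with an estimated correlation.

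The mitotic genes were higher in cKO PGCs at 1 dpf. The tables argued against scaling or abundant features as the cause, which move all genes alike. The median of all genes was -0.0149 and the lower quartile of the list 0.77. In pair 3 the tables also argued against the somatic cell types on the lists, with a highest somatic median of 0.0307 and a mitotic median of 0.51. A list median can miss a rise in few members, and cell types outside the lists were not tested. In pairs 1 and 2 somatic cells stay open (lower of the 2 highest somatic medians 1.87). An effect of smad1 loss whichever way it is lost also stays open, because the list median in the KD ran from -0.49 to -0.0486 over 4 scalings and how far the morpholino lowered the protein is not known. With 47 members passing alone in the real split and 0 in the highest other, the 10 splits are too few for a share under 0.05; the other 3 splits parting every pair also gave at most 0.

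BMP targets were lower in the KD and not in the cKO at 75% epiboly. A smaller share of somatic cells in the KD libraries stays open. The lower quartile of the axial mesoderm list was -0.145 and the upper quartile of the BMP targets -0.94, but 8 of the 12 axial members averaged under 5 TPM in controls, and the lower quartile of the other 4 was -2.15. Skin (median -1.38) and endoderm genes (-1.53) were lower with the BMP targets. BMP targets read from somatic cells in the sorting gate stay open (median 0.119 in control-morpholino minus control libraries). A biological reading, in which the morpholino acts earlier than editing or on other cells, was not tested. Chance cannot be excluded for the difference of 1.65, since 6 of 60 splits gave one as large (highest other 2.13). Of the 24 splits parting every cKO pair, 3 gave one as large, and of the 36 others 3 (highest 1.71).

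The counts of genes called were set against other splits of the libraries. With 0 genes called in the real split every split gives as many, so 4 of these counts say nothing about chance: 10 of 10 splits for the cKO at 75% epiboly (highest other 0), 60 of 60 for the average at 75% epiboly (real 0, highest other 5), 60 of 60 for the average at 1 dpf (real 0, highest other 7) and 100 of 100 for the stage difference of the cKO (real 0, highest other 68). In the last 3 no other split examined that parted every cKO pair called a gene. For the stage difference of the cKO the other splits were a random sample, so not every such split was examined. A split with 68 calls points to a structure of the samples. For the cKO at 1 dpf the 10 splits are too few for a share under 0.05, and 3 of 10 gave as many (real 1, highest other 65); the highest came from a split parting 1 pair, which points to a structure of the samples, and the other splits parting every pair gave at most 0. For the difference of the cKO and KD effects at 1 dpf 31 of 60 splits gave as many (real 33, highest other 239), 12 of them among the 24 parting every cKO pair (highest other 181), so chance cannot be excluded, and splits with so many calls point to a structure of the samples.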

How the results depend on the processing

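Depth is unknown for TPM, and the KD comparisons hold 2 libraries per group; leaving 1 out leaves a lone sample that is assumed to vary like the other group. The alternatives were chosen before the data were examined, except leaving out the abundant features, leaving out both libraries numbered 3, the counts adjusted over a list alone and the list tests of averages and differences, which were chosen after seeing the data. Where a value changed and no reason is given, the cause was not tested. The 0 calls for the cKO and for the average effect at 75% epiboly held under every alternative tried. The mitochondrial genome list could not be tested without the abundant features.

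For the cKO at 1 dpf, 8 genes were higher without both libraries numbered 3. For the KD at 75% epiboly, BMP targets passing alone numbered 0 with no filter and 0 without the trend. For the KD at 1 dpf, blood genes passing alone numbered 0 with no filter, 0 after quantile normalization, 0 with TMM-style scaling, 0 without the trend and 5 without abundant features, and the genes called were 10 higher and 33 lower at a minimum mean of 5 TPM and 1 and 9 without the trend. The stage difference of the cKO had 1 gene higher with no filter, and that of the KD 1 with a pseudocount of 0.1 and 1 at a minimum mean of 5 TPM. The average at 1 dpf had 4 genes higher after quantile normalization and 4 with TMM-style scaling. The difference at 75% epiboly had 3 genes higher and 6 lower with no filter. The difference at 1 dpf had 51 higher and 0 lower with a pseudocount of 0.1, 7 lower with no filter, 59 higher and 0 lower at a minimum mean of 5 TPM, 7 higher after quantile normalization, 5 with TMM-style scaling, 5 without the trend and 19 without abundant features, and its mitotic members passing alone numbered 20 after quantile normalization and 4 with TMM-style scaling.

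With the replicate number as a block, 12 genes were higher and 2 lower in the cKO at 1 dpf, 8 and 19 in the KD at 75% epiboly, and 130 and 736 in the KD at 1 dpf. In the KD the libraries share only a number, with correlations of deviations of 0.0777 at 75% epiboly and 0.601 at 1 dpf over 2 pairs each. The block also gave 12 BMP targets passing alone in the KD at 75% epiboly, and it ended the G1/S call in the KD at 1 dpf (adjusted p = 0.0778); it ended no other list call.

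With an estimated correlation, 0 lists were called in either direction in any of the 4 comparisons. For the cKO at 75% epiboly 1 list was higher at a minimum mean of 5 TPM and 1 without both libraries numbered 3, and 0 lists were lower after quantile normalization, without abundant features and without both libraries numbered 3. For the cKO at 1 dpf 1 list was lower without abundant features and 1 without both libraries numbered 3.

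Leaving out 1 library at a time gave these ranges. In the cKO at 1 dpf 0 to 45 genes were higher and 1 to 2 lower, with 31 to 47 mitotic members passing alone. In the KD at 75% epiboly 0 to 7 BMP targets passed alone. In the KD at 1 dpf 0 to 8 genes were higher and 0 to 33 lower, and 0 to 8 blood genes passed alone; 17 to 23 muscle genes did. The stage difference of the cKO had 0 to 3 genes higher and 0 to 1 lower, and the average at 1 dpf 0 to 2 and 0 to 1. The difference of the cKO and KD effects had 0 to 1 genes lower at 75% epiboly and 0 to 1356 higher and 0 to 55 lower at 1 dpf, with 1 to 43 mitotic members. Lists called numbered 0 to 3 higher and 1 to 4 lower in the cKO at 75% epiboly, 7 to 13 and 1 to 3 in the cKO at 1 dpf, 1 to 3 and 4 to 11 in the KD at 75% epiboly, and 3 to 10 and 3 to 8 in the KD at 1 dpf. Pearson's r ran from -0.0736 to 0.0543 for the cKO and KD at 75% epiboly, from -0.0177 to 0.133 at 1 dpf, from -0.0211 to 0.0379 between stages of the cKO and from -0.0369 to 0.0533 between stages of the KD.

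Correlations near 0 also changed sign under other settings. For the cKO and KD at 75% epiboly r was -0.0187 with a pseudocount of 0.1 and -0.00306 without abundant features, for the KD stages -0.0123 with a pseudocount of 0.1, and for the cKO stages -0.0193 at a minimum mean of 5 TPM and -4.5e-05 after quantile normalization.

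Of the genes given with values, none that passed a test over all genes reversed, and those that reversed were not called. In the cKO at 75% epiboly, the log2 difference of ved was 0.12 after quantile normalization, 0.0139 without abundant features and 2.11e-04 without both libraries numbered 3, and that of id1 -0.00652 without both libraries numbered 3. With 1 library left out, ved ran from -0.40 to 0.11, smad9 from -0.0842 to 0.54 and smad5 from -0.41 to 0.0109. In the cKO at 1 dpf, id1 was 0.0883 without both libraries numbered 3, and with 1 library left out id1 ran from -0.34 to 0.15, smad5 from -0.15 to 0.33, nanos3 from -0.18 to 0.10, ddx4 from -0.25 to 0.26 and krt4 from -0.50 to 5.13. In the KD at 75% epiboly, nanos3 was 0.26 after quantile normalization and 0.0942 without abundant features, and with 1 library left out nanos3 ran from -0.84 to 0.80, smad5 from -0.55 to 0.61, krt18a.1 from -3.74 to 0.43 and tbxta from -0.44 to 0.50. In the KD at 1 dpf, smad5 was 0.22 after quantile normalization and 0.29 with TMM-style scaling, nanos3 was 0.24 with TMM-style scaling, ddx4 was 0.11 after quantile normalization and 0.19 with TMM-style scaling, and with 1 library left out smad5 ran from -0.60 to 0.28, nanos3 from -1.35 to 0.89 and ddx4 from -1.01 to 0.45.

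For editing, summing the amplicons gave 0.297% in control PGCs, 0.282% in control somatic cells, 62.0% in cKO PGCs and 0.347% in cKO somatic cells, because the regions differ in level and in reads. Subtracting the control of the same cell type gave 80.8% and 35.9% at regions 1 and 3 in cKO PGCs, and 0.216%, 0.0165% and -0.00610% at the 3 regions in cKO somatic cells.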

Other observations

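Of the receptor Smads, smad1 was higher and smad5 lower at 1 dpf than at 75% epiboly in control PGCs. In the cKO experiment smad1 averaged 13.7 TPM at 75% epiboly and 138 TPM at 1 dpf, smad9 34.8 and 134 TPM, and smad5 95.1 and 36.0 TPM (n = 3 each). In control-morpholino PGCs smad1 averaged 9.88 and 197 TPM and smad5 98.8 and 23.3 TPM, while smad9 averaged 52.0 and 54.3 TPM (n = 2 each). The tables of the stages were processed separately, and the differences were not tested.

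Control libraries of the KD and cKO experiments differed in cell-type transcripts. At 1 dpf, 29 of 30 blood genes were higher in control-morpholino than in control libraries (median log2 difference 3.18), as were 25 of 26 muscle genes (2.29) and 19 of 22 axial mesoderm genes (1.91), while 35 of 36 maternal genes were lower (-1.38). At 75% epiboly all 12 FGF targets were lower (-1.10) and 21 of 22 endoderm, yolk and liver genes higher (1.25). Of the germ cell specification and germ plasm genes, 19 of 31 were lower at 75% epiboly (-0.99) and 20 of 32 at 1 dpf (-0.35). These tables were also processed separately, and the differences are given as values without a test.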
